A study of Arabidopsis thaliana with 4 samples.

How the data were processed

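RNA of whole Arabidopsis thaliana seedlings (Columbia) was sequenced, with 2 libraries at 0 h and 2 at 0.5 h after transfer to medium with 2.5 mM glutamine. Groups and replicate numbers were taken from the sample titles. Seedlings had grown for 14 days in liquid medium without nitrogen, with 16 h of light and 8 h of dark at 22 °C, per the labels' protocols. Libraries were made with a TruSeq RNA kit, per the labels' protocols.

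The deposited table holds RPKM values for 33602 genes. Its values are scaled by the authors with TMM (trimmed mean of M-values), as the file name says. The TAIR10 build and SAMtools, with no version, are named per the submitters' processing notes. The aligner, the counter and the strand setting are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. The deposited table also gives, per gene, a fraction that its column name describes as the highest share of multi-mapped reads. This fraction was above 0 for 8753 genes and above 0.5 for 2200.

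Multiplied by the deposited gene length, the RPKM values of each library lie on steps, with 0.5 read added to each gene. Reads recovered from these steps were whole, within a tolerance of 0.05 read, for 99.992 to 100.0% of the genes without multi-mapped reads and for 47.5 to 51.7% of those with them. Recovered totals were 26069135 and 27203588 reads at 0 h and 26075046 and 20429739 at 0.5 h. Genes without multi-mapped reads held 57.8 to 58.7% of the reads. A gene with 0 reads throughout a group was given a floor of 3 reads per library, which covers counting error only. Replicate libraries differed beyond counting error, with a chi-square per gene of 17.26 at 0 h and 16.03 at 0.5 h, and each was counted as a sample.

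Gene names and positions came from the TAIR10.1 annotation, in which 32835 loci were found by locus tag. Its build name differs from that of the deposited table, so no coordinates are printed, and the annotation was used for names and for overlapping or neighbouring genes. Of 2118 called genes placed in it, 553 overlapped another gene.

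Genes with a mean of at least 1 RPKM over the 4 libraries were tested with limma 3.58.1 in R 4.3.3, with an intensity trend, on log2(RPKM + 1), which understates the change of low genes. The model held the group alone, p-values were two-sided and adjusted by Benjamini-Hochberg, and the threshold was 0.05. The fit had 2 residual and 4.824 prior degrees of freedom. A 2-fold limit was applied to the fitted change after the test. Called genes numbered 2133, and in all 2133 the values of the groups did not overlap, as for 59.73% of tested genes against 33.33% by chance. Tables and plots used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

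Before the data were examined, 19 gene lists with 345 members, 22 gene families, the tests, most of the other settings and a rule for naming genes were fixed. The lists were nitrate uptake and assimilation, nitrogen-response regulators, ammonium assimilation and amino acid metabolism, ammonium and amino acid transporters, rapid touch and stress response, defence, jasmonate, early auxin response, cytokinin, abscisic acid and cold, anthocyanin, sugar starvation, phosphate starvation, heat shock, ribosome biogenesis, circadian clock, photosynthetic shoot tissue, root tissue and reference genes. Families were matched by gene symbols, synonyms and product names. The set matched as cytosolic ribosomal proteins, which is among the 22 and counted in the adjustment, also held disease resistance genes with like symbols and proteins of organelle type, and its result is not given. Lists and families with at least 5 tested members were tested with camera from limma, with a preset correlation of 0.01. P-values were adjusted over the lists and over the families. So set, camera judges a list against the spread across genes. With an estimated correlation 0 lists and 0 families passed. That setting rests on the 2 residual degrees of freedom, so it cannot decide whether correlation accounts for a result. The naming rule took the 5 largest rises and 5 largest falls among called genes whose groups did not overlap, the 2 members of each list with the smallest p, and, of the tissue and reference lists, the 2 with the highest mean. It gave 47 genes, and other members named beside them were chosen after their values were seen. A repeat of the rule among genes with a share of multi-mapped reads up to 0.05 was also made after the data were seen.

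Alternatives were a pseudocount of 0.1 or 5, no minimum or a minimum of 5 on the mean RPKM, median-of-ratios or quantile scaling, limma without the trend or with robust estimation, a replicate block, leaving out each library, leaving out organelle genes, an estimated correlation, and fry. After the data were seen, limma-voom on recovered reads and leaving out genes with a share of multi-mapped reads above 0.05 were added. A count test planned for recovered reads was not run, because the deposited unit is RPKM and genes with multi-mapped reads hold fractions of reads.

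The limma step was tested on 20 simulated data sets of 2 libraries against 2. It called 98.9% of genes raised by 2 on the log2 scale, 78.11% of those raised by 1, 70.69% of those lowered by 1 and 94.02% of those lowered by 2. Of all calls 9.671% were false, above the nominal 5%. Camera called 4 of 359 unshifted lists and 10 of 10 shifted ones. Each gene was simulated independently, with a spread shared by genes of like level. Camera was thus not tested on lists whose members vary together. In the data the estimated correlation was 0.587 for the nitrate list and 0.387 for the touch and stress list. The share of false calls depends on how many genes were changed and holds for this setting only.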

Results

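Whole Arabidopsis thaliana seedlings of the Columbia accession, 14 days old and raised without nitrogen, were sampled before (0 h) and 0.5 h after transfer to the same medium with 2.5 mM glutamine. RNA of each time was sequenced from 2 samples, and the comparison asks which transcripts respond early to glutamine. The 2 libraries at 0 h held 26069135 and 27203588 reads in genes, and those at 0.5 h held 26075046 and 20429739. The 2nd library at 0.5 h had the highest share of chloroplast reads, 0.379% against 0.0569 to 0.0974% in the other 3. It also had the highest share of nuclear ribosomal RNA, 0.851% against 0.270 to 0.355%. Seedlings transferred without glutamine, or sampled at the later time without transfer, were not among these samples, so the comparison holds glutamine, transfer and time together. The labels do not say that the samples came from separate cultures. Limma p-values rest on the spread between these libraries only, and not on each gene's own spread alone. The spread of each gene is drawn toward that of genes of like level, with 4.824 prior against 2 residual degrees of freedom. Camera p-values with a preset correlation judge a list against the spread across genes, not between libraries.

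At 0.5 h, the gene lists for nitrate assimilation, touch and stress, defence and heat shock were higher, and those for photosynthetic shoot tissue, the clock, sugar starvation and early auxin response were lower, by camera with a preset correlation. With an estimated correlation 0 of these 8 lists passed (camera adjusted p = 0.55 to 0.67). That setting rests on the 2 residual degrees of freedom, so it could pass few lists whatever their correlation. The estimates for photosynthetic shoot (-0.00062) and clock (-0.0298) were below the preset 0.01, yet neither passed. With fry, which does not compare a list with other genes, photosynthetic shoot and clock passed (adjusted p = 0.016 and 0.023). The others of these 8 did not (fry adjusted p = 0.095 to 0.20). Of 18039 genes tested with limma, 1211 were higher and 922 lower at a Benjamini-Hochberg adjusted p below 0.05. A fitted change of at least 2-fold was reached by 504 of the genes that rose and 246 of those that fell. Values are given as mean RPKM ± SD (n = 2 per time). Log2 fold changes are on the log2(RPKM + 1) scale with the limma standard error, which uses the spread so adjusted.

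The largest rises with few shared reads were those of AT5G54720, an ankyrin repeat protein gene, CML38 (AT1G76650), a calmodulin-like calcium sensor, and AT1G06475, an uncharacterized gene. AT5G54720 went from 1.63 ± 0.381 to 20.3 ± 14.2 RPKM (log2 fold change 2.84 ± 0.43, limma adjusted p = 0.011). It had 10.25 and 30.3 RPKM in the 0.5 h libraries. Its call ended with robust estimation and without a minimum on the mean RPKM. CML38 went from 46.3 ± 7.77 to 243 ± 51.2 RPKM (2.36 ± 0.20). AT1G06475 went from 0.680 ± 0.802 to 7.01 ± 0.679 RPKM (2.34 ± 0.32). AT1G06475 overlaps another annotated gene. Since the strand setting of the counting is not given in the sources used here, reads of both genes cannot be told apart. Among the other genes of the naming rule, this limit holds for UBQ6, GLT1, GAD4, TCH3, F3H, HSP101 and LNK2. It also holds for NUC1, SWA1, LHCB1.3, PYK10 and A1, which were not called. MAKR6 (AT5G52900), coding for a membrane-associated kinase regulator, fell from 32.5 ± 1.35 to 3.602 ± 0.0928 RPKM (-2.86 ± 0.12, limma adjusted p = 0.00061). AT1G64590, an NAD(P)-binding Rossmann-fold protein gene, fell from 58.1 ± 12.3 to 8.34 ± 0.436 RPKM (-2.65 ± 0.17). LHCB2.1 (AT2G05100) fell from 284 ± 48.0 to 42.4 ± 25.6 RPKM (-2.84 ± 0.38), with a share of multi-mapped reads of up to 0.44.

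The remaining 4 of the 10 most changed genes had a highest share of multi-mapped reads over the libraries of 1 and are uncertain. AT3G02468 and UBQ6 (AT2G47110), a ubiquitin gene, held 0 recovered reads in both 0.5 h libraries. Taking 3 reads per library as the floor, their listed values were at least 3840-fold and at least 1290-fold lower, which holds for the reads given to these gene models only. At 0 h AT3G02468 held as many reads as SAMDC (AT3G02470), 12446.75 and 12508, and UBQ6 as many as its neighbour AT2G47115, 4354 and 3977, within a tolerance of 0.05 read. Added together, the reads of each pair changed by 0.13 and -0.07 on the log2 scale. The gene TPS-CIN at AT3G25830, a terpene synthase, held 0 recovered reads at 0 h, and its listed value was at least 79.2-fold higher at 0.5 h. The reads of AT3G25830 and its copy AT3G25820 together changed by -0.89. SPL13B (AT5G50670), a squamosa-promoter-binding transcription factor, was fitted 3.04 ± 0.75 higher (limma adjusted p = 0.045), and together with its copy SPL13A the change was 1.24.

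**Figure D1:**
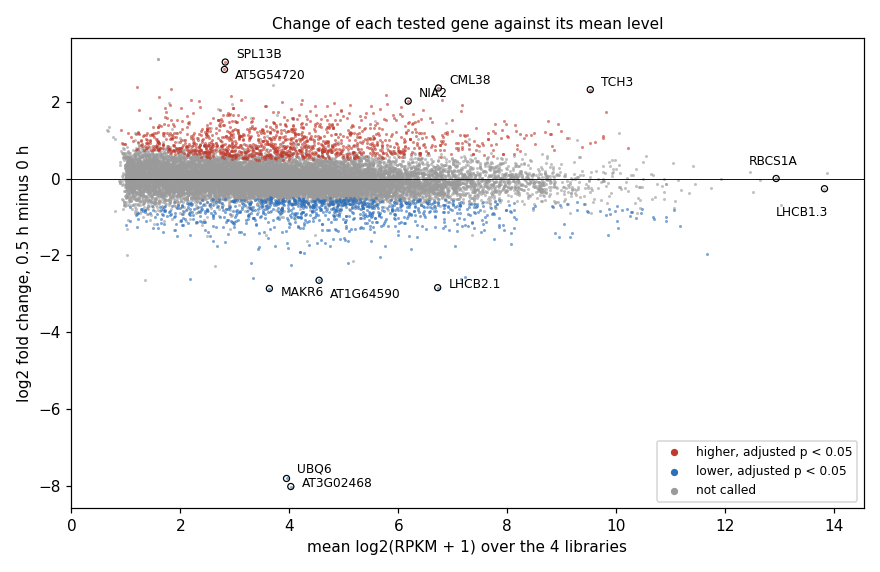
Log2 fold change from 0 h to 0.5 h (vertical axis) against the mean log2(RPKM + 1) over the 4 libraries (horizontal axis) for the 18039 tested genes, with red points for the 1211 that were higher and blue points for the 922 that were lower at a limma adjusted p below 0.05. UBQ6 and AT3G02468 lie near -8, far below all other genes, and both share their reads with another gene.

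Nitrate uptake and assimilation genes were higher as a list (median log2 fold change 0.91; camera adjusted p = 0.0021, and adjusted p = 0.67 with an estimated correlation). Of 16 tested members 9 rose and 2 fell, with the same 9 and 2 when adjusted over the list alone. NIA2 (AT1G37130), a nitrate reductase, rose from 35.3 ± 6.57 to 146 ± 22.1 RPKM (2.02 ± 0.19, limma adjusted p = 0.0047), and the other nitrate reductase gene, NIA1 (AT1G77760), from 7.28 ± 4.81 to 24.6 ± 5.12 RPKM (1.75 ± 0.38). NPF6.3 (AT1G12110), a nitrate transporter, rose from 77.1 ± 4.12 to 181 ± 7.90 RPKM (1.22 ± 0.14, limma adjusted p = 0.0060). The nitrite reductase gene NIR1 rose from 148 ± 48.5 to 331 ± 35.3 RPKM. UPM1 of siroheme synthesis, the ferredoxin-NADP reductases RFNR1 and RFNR2 and the glucose-6-phosphate dehydrogenases G6PD2 and G6PD3 rose as well. The 2 members that fell were NPF7.3, a transporter that loads nitrate into the xylem, by 1.25 ± 0.21, and CLC-A, a vacuolar nitrate exchanger, by 0.91 ± 0.13 on the log2 scale. The high-affinity transporter gene NRT2.1 had 49.8 ± 26.9 and 68.1 ± 0.785 RPKM at 0 and 0.5 h, which did not pass (limma adjusted p = 0.32).

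Nitrogen-response regulators as a list were not past camera (median 0.13, adjusted p = 0.19). Of 22 tested members 1 rose and 2 fell, and 5 rose and 2 fell when adjusted over the list alone. BT2 (AT3G48360), a BTB-domain regulator, went from 142 ± 42.1 to 333 ± 78.6 RPKM (1.24 ± 0.25). BZIP1 (AT5G49450), a leucine-zipper transcription factor, went from 106 ± 29.2 to 57.2 ± 0.790 RPKM (-0.85 ± 0.20), with all reads shared equally with AT5G49448. HRS1 (AT1G13300) fell by 1.16 ± 0.29 on the log2 scale.

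Ammonium assimilation and amino acid metabolism showed changes in both directions, with 4 of 26 tested members higher and 2 lower (4 and 3 adjusted over the list alone; median -0.17, camera adjusted p = 0.51). The median was -0.27 without the 1st library at 0.5 h and -0.05 without the 2nd. GLT1 (AT5G53460), the NADH-dependent glutamate synthase, rose from 34.1 ± 1.77 to 66.8 ± 7.12 RPKM (0.95 ± 0.14, limma adjusted p = 0.012). GAD4 (AT2G02010), a glutamate decarboxylase, rose from 2.41 ± 0.446 to 6.15 ± 1.03 RPKM. Both proline dehydrogenase genes rose, PRODH1 by 1.06 ± 0.18 and PRODH2 by 1.01 ± 0.17 on the log2 scale. The cytosolic glutamine synthetase gene GLN1-1 and the aspartate aminotransferase gene ASP3 fell by 0.69 ± 0.15 and 0.70 ± 0.17. ASN1, coding for asparagine synthetase, had 301 ± 38.6 and 267 ± 25.8 RPKM and did not pass. Among ammonium and amino acid transporters 1 of 17 rose and 5 fell, as also adjusted over the list alone (median -0.11, camera adjusted p = 0.34). Without the 1st library at 0 h this list passed (median -0.20, camera adjusted p = 0.042), and without the 2nd at 0 h its median was 0.12 (camera adjusted p = 0.80). Without the 1st and the 2nd at 0.5 h the medians were -0.07 and -0.02. CAT1 (AT4G21120), a cationic amino acid transporter, fell from 21.6 ± 2.21 to 11.1 ± 0.977 RPKM, and the ammonium transporter AMT1-2 (AT1G64780) from 8.45 ± 1.63 to 3.72 ± 0.744 RPKM. AMT1-3, AAP1 and AAP4 also fell, and AAP5 rose by 0.66 ± 0.14.

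Rapid touch and stress genes, chosen because transfer itself handles the seedlings, were higher as a list (median 0.54, camera adjusted p = 7.5e-05; adjusted p = 0.56 with an estimated correlation). Of 24 tested members 10 rose and 2 fell, and 16 rose and 4 fell adjusted over the list alone. TCH3 (AT2G41100), a calmodulin-like protein first known from touch, rose from 330 ± 46.7 to 1666 ± 382 RPKM (2.32 ± 0.22), and the xyloglucan-modifying TCH4 from 496 ± 75.4 to 1637 ± 180.4 RPKM. The cold-response factors CBF1 and CBF2 fell by 0.87 ± 0.16 and 0.89 ± 0.22 on the log2 scale. The calmodulin-like family, as matched by gene and product names, was higher too, with 8 of 11 tested members risen. Adjusted over the family alone, 8 rose and 1 fell. Its camera adjusted p was 8.1e-06, and 0.92 with an estimated correlation. The risen CML38, TCH3, TCH2 and CML37 are also members of the touch and stress list, so these results are not separate.

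Defence and pattern-triggered immunity genes were higher as a list (median 0.57, camera adjusted p = 3.5e-05; adjusted p = 0.55 with an estimated correlation). Of 27 tested members 12 rose and 2 fell, and 14 and 3 adjusted over the list alone. Without the 2nd library at 0 h the median was 0.34 (camera adjusted p = 0.00010). RBOHD (AT5G47910), the NADPH oxidase of the immune oxidative burst, rose from 12.99 ± 0.385 to 40.5 ± 3.84 RPKM (1.57 ± 0.13). CBP60G (AT5G26920), a regulator of salicylic acid synthesis, rose from 15.2 ± 1.63 to 42.6 ± 6.65 RPKM (1.42 ± 0.16). WRKY18, MKK4 and SARD1 rose, whereas WRKY53, with a share of multi-mapped reads of up to 0.361, and the receptor kinase gene FRK1, often used as a marker of pattern-triggered immunity, fell by 0.57 ± 0.13 and 0.79 ± 0.19 on the log2 scale.

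Jasmonate genes split, with 7 of 20 tested members higher and 4 lower (11 and 4 adjusted over the list alone; median 0.41, camera adjusted p = 0.051). AOC3 (AT3G25780), an allene oxide cyclase, rose from 9.30 ± 1.93 to 31.4 ± 2.16 RPKM (1.67 ± 0.16), and LOX4 (AT1G72520), a lipoxygenase, from 3.49 ± 0.119 to 8.34 ± 0.354 RPKM. The repressor genes JAZ1, JAZ5, JAZ6 and JAZ10 rose. AOC1, AOC2, LOX2 and JAZ3 fell. The list passed camera under 7 other settings, among them without the 1st library at 0 h (adjusted p = 0.042) and without the 1st at 0.5 h (0.012), and its adjusted p over all settings ran from 0.012 to 0.56.

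Heat shock genes were higher as a list, with 5 of 12 tested members risen and 0 fallen, also adjusted over the list alone (median 0.92, camera adjusted p = 0.00018; adjusted p = 0.56 with an estimated correlation). Like the touch and stress list, this list was fixed because the groups differ also in transfer and in time of day. HSFA2 (AT2G26150), a heat-induced transcription factor, rose from 10.6 ± 1.15 to 43.4 ± 16.6 RPKM (1.89 ± 0.25), and the chaperone HSP101 (AT1G74310) from 8.24 ± 1.82 to 25.6 ± 6.74 RPKM. The wider family of heat shock proteins had 9 of 59 members risen (9 adjusted over the family alone; median 0.19, camera adjusted p = 0.0075, and adjusted p = 0.92 with an estimated correlation), and its camera call ended without the 2nd library at 0 h (adjusted p = 0.053) and without the 1st at 0.5 h (median 0.07, adjusted p = 0.17).

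**Figure D2:**
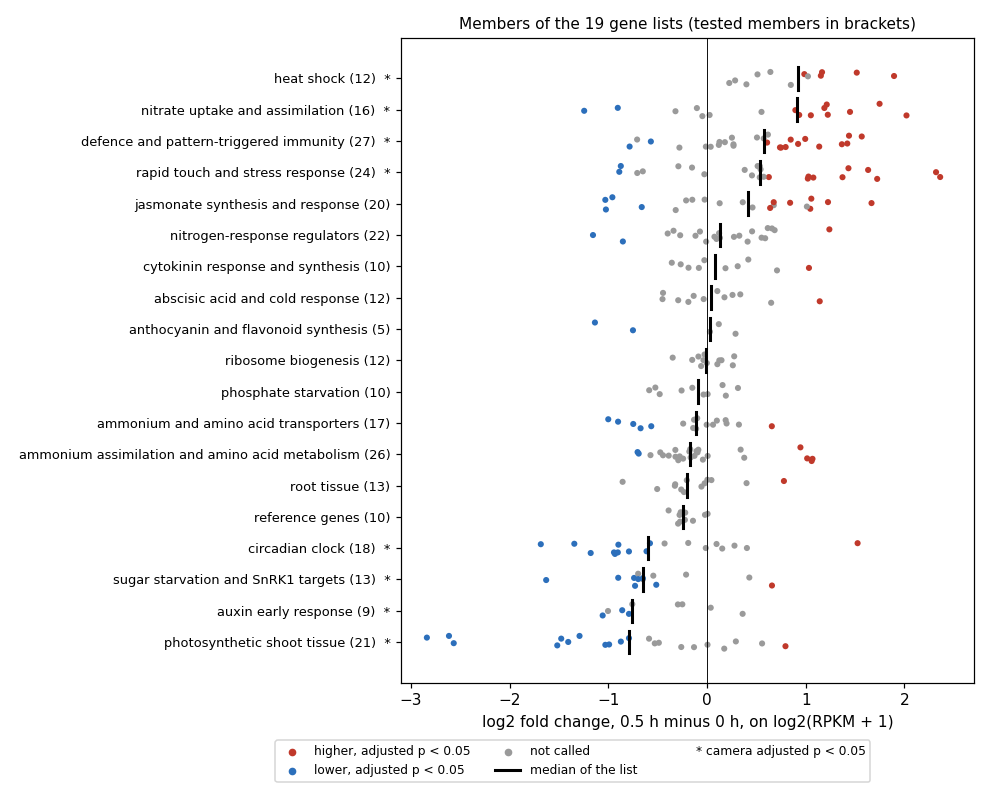
Log2 fold change from 0 h to 0.5 h (horizontal axis) of each tested member of the 19 gene lists (1 line per list, ordered by median); red and blue points passed the limma test and black bars are list medians. Heat shock (median 0.92) and nitrate assimilation (0.91) stand at the upper end and photosynthetic shoot genes (-0.79) at the lower end.

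Photosynthetic shoot genes were lower as a list (median -0.79, camera adjusted p = 3.5e-05; adjusted p = 0.55 with an estimated correlation). Of 21 tested members 11 fell and 1 rose, and 14 and 2 adjusted over the list alone. Among chlorophyll a/b-binding protein genes, the falls of LHCB2.1 (-2.84 ± 0.38), LHCB1.1 (-2.62 ± 0.25) and LHCB2.2 (-2.57 ± 0.38) were the largest, with shares of multi-mapped reads of up to 0.44, 0.226 and 0.449. With few shared reads, LHCA4 fell from 1531 ± 63.1 to 549 ± 13.03 RPKM, LHCB6 from 945.5 ± 4.38 to 356 ± 21.2 RPKM and LHCA3 from 1632 ± 27.0 to 666 ± 14.8 RPKM. The members with the highest means were LHCB1.3 (AT1G29930), at 15868 ± 183 and 13238 ± 447 RPKM, and RBCS1A (AT1G67090), a RuBisCO small subunit gene, at 7822 ± 199 and 7848 ± 344 RPKM, and neither passed (limma adjusted p = 0.44 and 0.99). RBCS1B, whose share of multi-mapped reads reached 0.486, rose by 0.79 ± 0.19. The 2nd library at 0.5 h had the highest chloroplast share of reads, 0.379%, and without it the list median was -0.88 (camera adjusted p = 1.5e-05).

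Circadian clock genes were lower as a list (median -0.60, camera adjusted p = 0.0018; adjusted p = 0.55 with an estimated correlation), with 10 of 18 tested members lower and 1 higher (11 and 1 adjusted over the list alone). This list too was fixed because the groups differ also in transfer and in time of day, which cannot be told apart from glutamine here. LNK2 (AT3G54500), a clock co-activator, fell from 39.6 ± 1.11 to 11.8 ± 3.34 RPKM (-1.69 ± 0.19), and RVE8 (AT3G09600), a morning-phased MYB factor, from 7.69 ± 0.194 to 2.44 ± 0.485 RPKM (-1.35 ± 0.16). CCA1, PRR5, PRR7 and GI also fell. BOA rose by 1.53 ± 0.19.

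Sugar starvation genes were lower as a list (median -0.65, camera adjusted p = 0.0013; adjusted p = 0.56 with an estimated correlation), with 7 of 13 tested members lower and 1 higher (10 and 2 adjusted over the list alone). DIN2 (AT3G60140), a dark-induced beta-glucosidase, fell from 78.9 ± 15.5 to 24.9 ± 5.71 RPKM (-1.63 ± 0.21). TPS10 (AT1G60140), a class II trehalose-phosphate synthase, fell from 48.2 ± 0.674 to 25.3 ± 0.689 RPKM. BZIP53, which rose by 0.66 ± 0.15, shared all reads equally with AT3G62422.

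**Figure D3:**
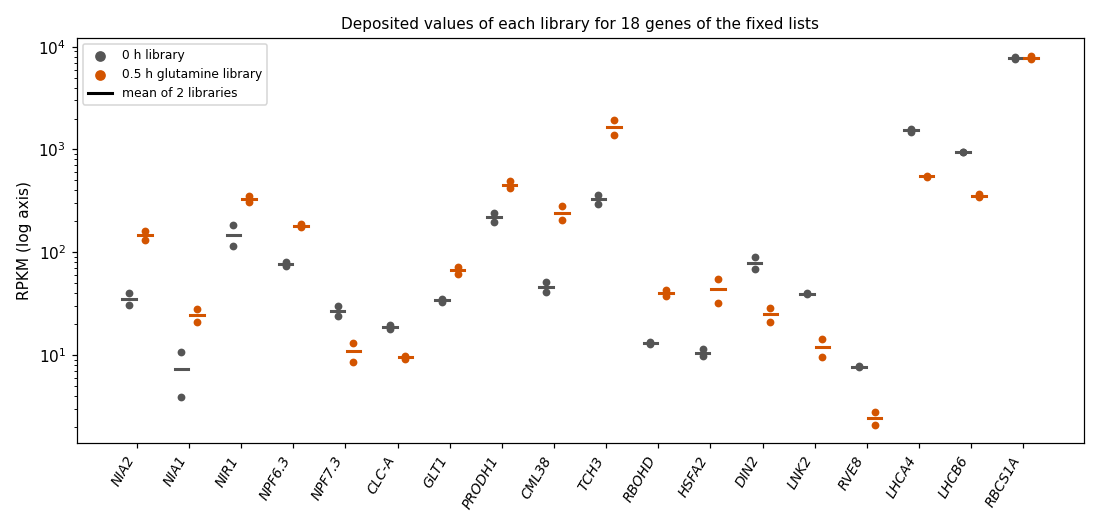
RPKM of each library (vertical log axis) for 18 genes of the lists, with grey points at 0 h, orange points at 0.5 h and bars for the mean of 2 libraries. For every gene shown except RBCS1A the 2 times do not overlap. These are called genes, and the 2 times do not overlap in any of the 2133 called genes. RBCS1A had means of 7822 and 7848 RPKM.

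Early auxin-response genes were lower as a list (median -0.76, camera adjusted p = 0.023; adjusted p = 0.56 with an estimated correlation), with 3 of 9 tested members lower and 0 higher (4 and 0 adjusted over the list alone). GH3.5 (AT4G27260), an auxin-conjugating enzyme, fell from 37.0 ± 0.819 to 17.3 ± 1.26 RPKM, and IAA2 (AT3G23030), an auxin-response repressor, from 226 ± 22.7 to 124 ± 2.18 RPKM. Without the 2nd library at 0 h the list had a camera adjusted p of 0.072, and without the 2nd at 0.5 h 0.22, with a median of -0.27.

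Lists for other hormones and nutrients were not past camera. Of 10 cytokinin genes IPT3 (AT3G63110), a cytokinin-synthesis enzyme, rose from 1.52 ± 0.0928 to 4.17 ± 0.483 RPKM and no other passed, also adjusted over the list alone (median 0.08, camera adjusted p = 0.44). CYP735A2 (AT1G67110) had 1.15 ± 0.697 and 2.42 ± 0.110 RPKM. Of 12 abscisic acid and cold genes LTI30 (AT3G50970), a dehydrin, rose from 104 ± 27.9 to 226 ± 7.57 RPKM and no other passed, also adjusted over the list alone (median 0.03, camera adjusted p = 0.68); COR47 (AT1G20440) had 322 ± 82.0 and 497 ± 21.4 RPKM. Of 5 tested anthocyanin genes 2 were called lower, also adjusted over the list alone. These were MYBL2 (AT1G71030), a repressor of anthocyanin synthesis, by 1.14 ± 0.15 on the log2 scale, and F3H (AT3G51240), whose reads are shared with the overlapping AT3G51238 (limma adjusted p = 0.0495). F3H held 60 and 71 reads and AT3G51238 0 at 0 h, whereas at 0.5 h both held 27.5 and 16.5. Added together, the reads of this pair changed by -0.51 on the log2 scale, so the call of F3H is uncertain. The anthocyanin median was 0.03 while its mean was -0.29 and camera pointed down (adjusted p = 0.41), and the list passed fry, which does not compare it with other genes (adjusted p = 0.016). Of 10 phosphate starvation genes and of 12 ribosome biogenesis genes 0 passed limma, over all genes or adjusted over the list alone, with 2 and 1 of them below an unadjusted p of 0.05, and limma-voom on recovered reads called 0 of either list. SPX1 (AT5G20150) had 13.1 ± 0.302 and 8.88 ± 1.99 RPKM, PHT1-1 (AT5G43350) 35.4 ± 8.02 and 23.4 ± 6.33, NUC1 (AT1G48920) 163 ± 9.67 and 128 ± 4.65, and SWA1 (AT2G47990) 10.9 ± 0.449 and 13.2 ± 1.22 RPKM. The phosphate list had a median of -0.09 (camera adjusted p = 0.44) and the ribosome list a median of -0.01 with a mean of 0.02 and a direction of up (camera adjusted p = 0.75). These medians moved or changed sign with 1 library left out, and 0 of the 5 lists passed camera then. Without the 1st and the 2nd library at 0 h and the 1st and the 2nd at 0.5 h, in this order, they were -0.13, 0.30, 0.12 and 0.06 for cytokinin and 0.25, -0.22, 0.18 and -0.08 for abscisic acid and cold. They were 0.02, -0.03, -0.05 and -0.09 for anthocyanin, -0.07, -0.14, -0.22 and -0.11 for phosphate, and 0.07, -0.02, -0.0095 and -0.0025 for ribosome biogenesis.

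Root tissue markers had a median of -0.21 (camera adjusted p = 0.75), with SHR risen and 12 of 13 not called, also adjusted over the list alone. Without the 1st library at 0 h the list passed, with a median of -0.54 (camera adjusted p = 0.034), while without the 2nd at 0 h, the 1st at 0.5 h and the 2nd at 0.5 h its medians were 0.13, -0.57 and 0.24. PYK10 (AT3G09260), a root beta-glucosidase, had 215 ± 81.4 and 166 ± 0.593 RPKM, and PER72 (AT5G66390) 26.7 ± 0.597 and 22.7 ± 7.09 RPKM. Of the 10 reference genes 0 passed limma, over all genes or adjusted over the list alone, and 0 passed limma-voom, with 1 below an unadjusted p of 0.05 (median -0.25, camera adjusted p = 0.10). UBQ10 (AT4G05320) had 1491 ± 25.9 and 1279 ± 131 RPKM, and the elongation factor gene A1 (AT5G60390) 661 ± 72.7 and 546 ± 51.1 RPKM.

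Of the 22 gene families 6 passed camera, and with an estimated correlation all 6 had adjusted p = 0.92. Cell-wall-loosening families were higher: 8 of 24 xyloglucan endotransglucosylase/hydrolase genes rose and 1 fell (9 and 1 adjusted over the family alone; median 0.37, camera adjusted p = 0.0092), and 4 of 16 expansin genes rose (6 adjusted over the family alone; median 0.54, camera adjusted p = 0.0075). The 4 expansin genes included PNP-A, coding for a natriuretic peptide. XTH18 rose by 1.54 ± 0.18 and EXPA6 by 1.47 ± 0.24. The touch and stress list also holds the xyloglucan-modifying TCH4, so the xyloglucan family result may not be separate from it. Receptor-like kinases were higher, with 31 of 234 risen and 6 fallen (35 and 8 adjusted over the family alone; median 0.14, camera adjusted p = 0.0075). Cytochrome P450 genes were lower, with 20 of 131 fallen and 11 risen (38 and 15 adjusted over the family alone; median -0.22, camera adjusted p = 0.023). CYP71B26 fell by 1.67 ± 0.13 on the log2 scale, and the brassinosteroid-synthesis genes DWF4 and BR6OX2 rose by 1.38 ± 0.16 and 1.08 ± 0.13. Without the 1st library at 0.5 h the camera calls of xyloglucan enzymes (median 0.08, adjusted p = 0.26), expansins (median 0.06, adjusted p = 0.35) and receptor-like kinases (median 0.11, adjusted p = 0.12) ended. Without the 1st at 0 h receptor-like kinases lost theirs too (median 0.06, adjusted p = 0.29), and the medians of xyloglucan enzymes and expansins were 0.06 and 0.35 (adjusted p = 0.0499 for both). The xyloglucan median was 0.69 without the 2nd at 0 h and 0.64 without the 2nd at 0.5 h. Cytochrome P450 genes lost their call without the 2nd at 0 h (median -0.19, adjusted p = 0.13) and the 2nd at 0.5 h (median -0.14, adjusted p = 0.059). Among the 16 families not past camera, 9 of 59 WRKY genes rose and 6 fell and 9 of 67 ERF/DREB genes rose and 5 fell. Peroxidases passed without the 2nd library at 0.5 h (median 0.27, adjusted p = 0.00087) and UMAMIT transporters without the 1st at 0 h (median -0.23, adjusted p = 0.0080).

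All counts rest on 2 libraries per time. Without the 1st library at 0 h 553 genes were higher and 234 lower, without the 2nd 561 and 393, and without the 2nd at 0.5 h 489 and 251, each time with the lone library assumed to vary like the other group. Without the 1st at 0.5 h the counts were 1131 and 787, of which 377 fell at least 2-fold. Leaving out 1 library ended the call of 11 of the 35 called genes named by the fixed rule: SPL13B, TPS-CIN (AT3G25830), BT2, BZIP1, GAD4, CAT1, AMT1-2, IAA2, IPT3, LTI30 and F3H. Without the minimum on mean RPKM, 163 genes were higher and 85 lower, and 21 of the 35 lost their call. With robust estimation SPL13B and AT5G54720 lost theirs.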

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

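Of the alternatives, limma-voom on recovered reads and leaving out genes with shared reads were chosen after the data were seen. Genes called under any alternative and in the result reported had the same direction in both. With a pseudocount of 5, genes at least 2-fold higher numbered 231 and 2-fold lower 136. Without a minimum on the mean RPKM 163 genes were higher and 85 lower, 149 and 67 of them at least 2-fold. There 25242 genes were tested and the prior degrees of freedom fell from 4.824 to 2.508. Leaving out each library gave 489 to 1131 genes higher and 234 to 787 lower, and 374 to 627 and 176 to 377 at least 2-fold. Without the 1st library at 0 h 553 were higher and 234 lower, without the 2nd 561 and 393, and without the 2nd at 0.5 h 489 and 251. Without the 1st at 0.5 h 377 genes were at least 2-fold lower. These fits have 1 library fewer. Lists past camera numbered 7 to 11 and families 2 to 7, with 2 without the 1st library at 0.5 h. With an estimated correlation, which rests on 2 residual degrees of freedom, 0 lists and 0 families passed. With fry 0 families and 3 lists passed. These were photosynthetic shoot (fry adjusted p = 0.016), clock (0.023) and anthocyanin (0.016), the last of which was not past camera. For the changes with other settings than fewer libraries, the cause was not tested.

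The replicate numbers are not shown to pair the samples, and deviations of same-numbered libraries had a correlation of -0.0778 over genes. With a replicate block 1127 genes were higher and 834 lower. Limma-voom gave 1315 and 1088, and leaving out genes with shared reads 1189 and 954. Of named genes, 5 values turned, none of them called: RBCS1A to -0.0216 without the 1st library at 0 h and -0.0404 without the 2nd at 0.5 h, PYK10 to 0.0700 without the 2nd at 0 h, PER72 to 0.0483 without the 2nd at 0.5 h, and UBQ10 to 0.0944 with quantile scaling. Leaving out each library gave -0.0404 to 0.0492 for RBCS1A, -0.716 to 0.0700 for PYK10 and -0.572 to 0.0483 for PER72. In 672 of 732 comparisons of named genes with an alternative the call and direction were kept, in 53 the call was lost and in 2 gained. The planned count test was not run, since the deposited unit is RPKM and genes with multi-mapped reads hold fractions. The 2nd library at 0.5 h, with 20429739 reads, was the shallowest.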

Other observations

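All tests in this part were chosen after the results were seen, and the set of Calvin cycle genes was narrowed after its first result. Among 220 product names of the annotation with at least 8 tested genes, 6 held more higher genes than expected. The limit was an adjusted p below 0.05 by a hypergeometric test over 16545 genes. This test takes genes as independent, also where they change together, and its p-values do not measure the spread between libraries. Genes named calcium-binding EF-hand family proteins had 11 of 28 risen against 1.86 expected (adjusted p = 0.00035). None was in the calmodulin-like family as matched by name, but they are not a separate group, since AT2G41090, MSS3 and others are also known as calmodulin-like genes. AT2G41090 rose from 16.8 ± 0.721 to 67.2 ± 12.9 RPKM (SD, n = 2) and MSS3 from 49.6 ± 0.853 to 122.5 ± 10.1 RPKM. Intracellular immune receptors of the TIR-NBS-LRR class had 14 of 48 risen and 1 fallen against 3.19 expected (adjusted p = 0.00037), 8 of the risen with few shared reads. AT4G14370 rose from 3.06 ± 0.251 to 12.45 ± 2.28 RPKM and AT5G58120 from 2.85 ± 0.471 to 10.04 ± 1.04 RPKM. Without the 2nd library at 0.5 h 7 of the risen EF-hand genes were called. Of the risen receptor genes 7 were called without the 1st library at 0 h, 8 without the 2nd at 0 h and 7 without the 2nd at 0.5 h.

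Hydroxyproline-rich late embryogenesis abundant proteins had 8 of 22 genes risen against 1.46 expected (adjusted p = 0.0074), among them NDR1 of disease resistance, by 1.02 ± 0.16 on the log2 scale. Protein phosphatases 2C had 12 of 50 risen and 3 fallen against 3.32 (adjusted p = 0.0087), protein kinases 31 of 230 risen and 9 fallen against 15.3 (0.012), and GRAS transcription factors 6 of 17 risen against 1.13 (0.041), with HAM3 from 8.38 ± 0.508 to 23.65 ± 0.119 RPKM. Without the 1st library at 0 h, 3 of the risen phosphatases, 11 of the kinases and 1 of the GRAS genes were called. Without the 2nd at 0 h, 4 of the hydroxyproline-rich proteins, 2 of the phosphatases, 14 of the kinases and 2 of the GRAS genes were called, and without the 2nd at 0.5 h 3 phosphatases, 14 kinases and 1 GRAS gene.

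Of the 10 most changed genes, 4 share nearly all reads with another gene. Their changes may come from reads given to another gene model. Added to its partner, AT3G02468 changed by 0.13, UBQ6 by -0.0702 and the terpene synthase AT3G25830 by -0.89, where a loss or gain of the listed size is not seen. SPL13B with SPL13A still changed by 1.24, so reassignment alone does not account for that rise. No biological explanation was tested.

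The 20 light-harvesting genes had a median of -1.35 with 14 fallen. Of 34 other nuclear genes with photosystem product names, which include an assembly factor, 13 fell and 0 rose (median -0.48). Among these 13, AT1G51400 had a share of multi-mapped reads of up to 0.85. The 16 RuBisCO small subunit and Calvin cycle genes had a median of -0.10, with 16 of 16 above the light-harvesting median (-0.08 and 23 of 23 before that set was narrowed). A smaller share of shoot tissue would lower these sets alike, so it is argued against as the whole cause, and a small part of the fall through it stays open. Reads given to near-identical copies are argued against too, since 14 of the 14 fallen genes fell by more than the loss of all multi-mapped reads could give. For the fall of the light-harvesting genes (median -1.35), another time of day, transfer and glutamine cannot be told apart, since all of them differ between the groups.

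Touch and stress genes (median 0.54) may have risen through handling and transfer instead of glutamine. These cannot be told apart, because no seedlings transferred without glutamine were among the samples.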
